A study of Mus musculus with 8 samples.

How the data were processed

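ChIP-seq was carried out on primary mouse bone marrow mesenchymal stem cells of 2 genotypes, per the labels. Chromatin was crosslinked with DTBP and formaldehyde and sheared to fragments of 200 to 500 bp, per the labels' protocols. The H3K9me3 immunoprecipitations carried yeast chromatin as a spike-in, per the series' design text, and whether it entered the peak calls is not given in the sources used here. That text names KDM4B antibodies from 2 suppliers without saying which library used which. It also names 2 sequencing instruments without assigning libraries to them, so an instrument batch could not be examined.

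Reads were aligned with Bowtie, handled with SAMtools, and peaks were called with MACS for the KDM4B samples and MACS2 for the others, per the submitters' processing notes, which list the builds mm9 and hg19. Their versions and thresholds are not given in the sources used here, except in the H3 WT table. Of the 6 files, 5 deposited by the authors hold only chromosome, start and end, with no height, score or p-value, so peaks in them could not be ranked by strength. The H3 WT table was written by MACS2 2.1.4 with a control, a q-value threshold of 0.05, 1 tag kept per position, an effective genome size of 1.87e+09 and an estimated fragment length of 76 bp, per the file headers. That estimate is close to the tag size of 74 bp and below the 200 to 500 bp of the sheared chromatin. Its deposited columns give the pileup signal at each summit, the fold enrichment over the local background, and the −log10 p-value and −log10 q-value. Per the file headers, total tags were 43787580 in the H3 WT library and 54306180 in its control, and the larger library was scaled to the smaller. Peaks were taken as called per sample, 1 file each; pooling is not stated. A peak count depends on depth, on the control and on the threshold, and these are unknown for 5 of the lists, so differences in peak number between lists can come from any of them.

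The build was checked on the positions: on 9 of 21 chromosomes the last peak lies beyond the last gene of the GRCm38.p6 gene table, for example at 152508057 on chromosome 7. That table was therefore of another build and was not used. The gene-level comparisons planned before the data were examined, by gene feature and by 13 fixed gene lists and 7 gene families, were not run, and the deleted gene Kdm4b was not located. The regions to be named were to be the 10 highest-scoring peaks of each main list absent from the other genotype, and up to 10 peaks shared by KDM4B WT and H3K9me3 KO. Without scores they were ranked by width instead, a choice made after the files were seen. The clusters given as ranges on chromosomes 1, 2, 3, 4, 5, 9, 11, 15, 17 and X were also chosen after the peaks were seen.

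Overlap meant at least 1 shared bp. Shares carry 95% exact binomial (Clopper-Pearson) intervals and numbers per Mb carry exact Poisson intervals; both cover counting error only, and neighbouring peaks are not independent. A count of 0 is given with the share that 3 counts would make. Densities use the span between the first and last peak of any list on each chromosome. Overlaps between lists were set against 1000 chance placements, in which the first list was shifted circularly by a random amount within that span on each chromosome, which keeps peak widths and spacing. They describe these libraries and are not a test of genotype. The profile around KDM4B midpoints used 100 such placements. Overlap counts were computed in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1 and checked against bedtools 2.31.1, which gave the same number in all 90 comparisons. On simulated data, in which 0, 5 or 20% of the 32017 KDM4B WT peaks were planted in an otherwise shifted H3K9me3 KO list, the excess over chance was -0.22, 4.59 and 18.9% of peaks. The shift removes regional density shared by the real lists, so this checks the calculation only and not the excess in the real lists.

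The alternatives were autosomes only, merging of peaks within 1 kb, overlap of at least 50% of the shorter peak, sharing within 1 kb, and uniform random placement. A score threshold could be applied to the H3 WT list alone. Chosen after seeing the data were a limit at the median width, shifts of 20 to 100 kb, and leaving out regions within 10 kb of H3 or KDM4B KO peaks.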

Results

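KDM4B is a histone demethylase that removes methyl groups from lysine 9 of histone H3, and H3K9me3, the trimethylated form of that residue, marks repressed chromatin. The study mapped both by chromatin immunoprecipitation sequencing (ChIP-seq) in mesenchymal stem cells, the bone marrow cells that can form bone, cartilage and fat. The cells came from mice in which Cre recombinase under the limb mesenchyme promoter Prx1 deletes Kdm4b (KO) and from mice with intact Kdm4b (WT), and were placed in osteogenic induction for 4 hours. The 6 deposited peak lists comprised KDM4B, H3K9me3 and total histone H3, each in 1 WT and 1 KO library. The 2 input samples, 1 per genotype, were not analysed here as peak lists. With 1 library per group there was no replicate check, so differences between genotypes are given without a test and intervals cover counting error only. Sequencing depth was given for 1 library, H3 in WT, which held 40420466 tags after duplicate filtering against 45099322 in its control. The depth behind the other lists is unknown. Positions are in mouse build mm9, and regions are named by position because no gene annotation of that build was used here.

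The first comparison asked where KDM4B was bound and whether its signal needed the gene. KDM4B was called at 32017 sites in WT cells and at 35 sites in KO cells, a ratio of 915. The WT peaks covered 24.2 Mb with a mean width of 755 bp, and the KO peaks covered 16.8 kb with a mean width of 481 bp. WT peaks lay on all 19 autosomes, the X and the Y, and 1916 of the 2216 windows of 1 Mb that held a peak of any list contained at least 1 of them. They were densest on chromosome 11, with 21.9 peaks per Mb, and chromosome 19, with 21.6 per Mb, and sparsest among autosomes on chromosome 18, with 8.94 per Mb. The densest single window was chromosome 7 from 87000001 to 88000000, with 132 peaks, followed by chromosome 10 from 80000001 to 81000000, with 123 peaks.

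Wide KDM4B domains made up a large part of the bound sequence. Peaks of 1 kb or more were 19.9% of the WT list and held 49.1% of its covered length. The widest, on chromosome 19 from 5821359 to 5850620, spanned 29.3 kb. It was followed by chromosome 14 from 63741118 to 63765427, with 24.3 kb, chromosome 10 from 59740042 to 59760358, with 20.3 kb, and chromosome 10 from 127023898 to 127043323, with 19.4 kb. None of the 32017 WT peaks, wide or narrow, overlapped a KDM4B peak of the KO library or an H3 peak. Of these 4 named domains, the chromosome 19 domain and the first chromosome 10 domain each contained 5 H3K9me3 peaks of the KO library, the second chromosome 10 domain contained 7, and the chromosome 14 domain contained 0. These counts were not set against regional density. The 1 Mb windows holding the chromosome 19 and the second chromosome 10 domain had 186 and 103 such peaks.

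The 35 KDM4B peaks of KO cells lay in a small set of regions that the other antibodies also recovered. They included 17 peaks at the start of the assembled chromosome 9, between 2999868 and 3038396, 3 peaks on chromosome 17 between 39979832 and 39985918, and 3 on chromosome 2 between 98502253 and 98507614. None of the 35 overlapped a KDM4B peak of WT cells, a count of 0 that allows a share of up to 8.57%, and chance placement of these peaks gave a mean of 0.504 overlaps. The nearest WT peak lay 1.55 kb from a KO peak, and the median distance was 378 kb. In contrast, 34 of the 35 overlapped an H3K9me3 peak both in WT and in KO cells, or 97.1% (95% exact binomial interval 85.1 to 99.9%). The exception lay on chromosome 9 from 120868443 to 120868668. At least 1 H3 list held 11 of the 35.

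Total H3, the histone background of the same genotypes, gave 38 peaks in WT and 28 in KO cells, covering 4.72 kb and 3.34 kb with mean widths of 124 and 119 bp. Of the WT peaks, 2 lay on the mitochondrial sequence, which carries no histones, so the H3 WT list holds some signal other than H3. The lists shared 18 peaks. The largest group in both lay on chromosome 5 between 14914979 and 15199963, with 13 WT and 10 KO peaks, a region where KDM4B had none and H3K9me3 had 1 peak in WT and 0 in KO. In the authors' table for WT, fold enrichment over the local background ranged from 1.63 to 16.6 with a median of 5.16. The highest value belonged to the peak on the X chromosome from 123312312 to 123312434. H3 peaks overlapped H3K9me3 peaks of the same genotype in 16 of 38 cases in WT and in 14 of 28 in KO, and overlapped no KDM4B peak of WT cells in either genotype.

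The second comparison asked how H3K9me3 was distributed with and without the demethylase. H3K9me3 was called at 943 sites in WT and at 55306 sites in KO cells, 58.6 times as many. On the mitochondrial sequence, which carries no histones, 5 of the KO peaks and 0 of the WT peaks were called, so the KO list holds some signal other than the mark. The covered length was 0.593 Mb in WT and 17.1 Mb in KO, a ratio of 28.8, lower than the ratio of peak numbers because the KO peaks were narrower. Merging peaks within 1 kb of each other gave 611 WT and 42246 KO regions. Mean width was 629 bp in WT and 309 bp in KO, and 20.8% of KO peaks had the smallest width in the list, 199 bp, against 10.9% of WT peaks at the same width. Peaks of 1 kb or more were 0.533% of the KO list and 10.4% of the WT list, and held 2.97% and 50.6% of the covered length. H3 peak numbers in the same genotypes differed by a ratio of 1.36 in the other direction. The H3 lists hold only 38 and 28 peaks, so this ratio does not show that the H3K9me3 libraries were comparable in depth or threshold. Of the KO peaks, 90, or 0.163%, lay within 10 kb of an H3 peak or a KDM4B peak of KO cells, against 70 of the WT peaks, or 7.42%.

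Broad H3K9me3 domains were recovered in both genotypes, whereas narrow WT peaks mostly were not. Of the 943 WT peaks, 410 overlapped a KO peak, or 43.5% (95% exact binomial interval 40.3 to 46.7%), while 1000 chance placements gave a mean of 16.4 and a highest value of 50. The observed number was 24.97 times the chance mean, and 7.97 to 44.4 times over the alternative settings. The share was 86.7% (78.4 to 92.7%) for the 98 peaks of 1 kb or more, 60.7% (55.9 to 65.4%) for peaks from 300 bp to under 1 kb, and 16.0% (12.6 to 19.8%) for peaks under 300 bp. The widest shared domains sat at the start of chromosome 11, where 73.4 kb was covered in WT and 73.7 kb in KO between 3000123 and 3102494. That block also held 1 KDM4B peak of WT cells, and 1 KDM4B peak and 1 H3 peak of KO cells, so other antibodies recovered parts of it too. A second shared block on chromosome 1, between 90106858 and 90207361, had 70.5 kb in WT and 74.5 kb in KO, and held 1 KDM4B peak of WT cells.

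**Figure D1:**
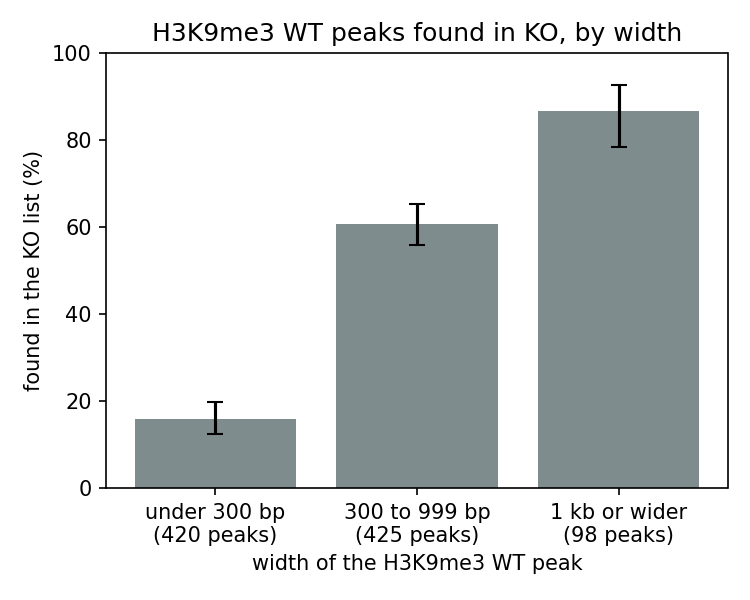
Share of H3K9me3 WT peaks (y axis, percent) that overlap an H3K9me3 KO peak, by width of the WT peak (x axis). Bars are shares over all peaks of the class in 1 library and error bars are 95% exact binomial intervals; the share is 16.0% for peaks under 300 bp and 86.7% for those of 1 kb or wider.

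A few broad WT regions were largely missing from the KO list. On chromosome 3 between 25416358 and 25456246, WT cells had 34 H3K9me3 peaks covering 30.3 kb, and KO cells had 10 peaks covering 3.79 kb. On chromosome 4 between 146802677 and 146911985, WT cells had 17 peaks covering 10.9 kb and KO cells had 2 covering 0.482 kb. Of the 13 WT peaks of 1 kb or more with no KO counterpart, 6 lay on chromosome 3 and 3 on chromosome 4. The widest was on chromosome 3 from 25428849 to 25431238, with 2.39 kb. KDM4B had no WT peak in either of these regions.

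The KO list, in which 54870 of the 55306 peaks overlapped no WT peak, was spread over the autosomes in clusters. All KO peaks together occupied 2074 windows of 1 Mb over all chromosomes, against 335 for WT. Chromosome 11 was densest, with 44.2 KO peaks per Mb, followed by chromosome 17 with 32.4 and chromosome 19 with 32.1, and chromosome 3 was sparsest among autosomes with 9.76. The densest windows were neighbours on chromosome 10, with 406 peaks from 80000001 to 81000000 and 388 from 79000001 to 80000000, where WT cells had 4 and 0. Apart from the mitochondrial sequence, the widest peak without a WT counterpart lay on chromosome 1 from 90172316 to 90175080, with 2.77 kb, and the next on chromosome 1 from 165243588 to 165246174, with 2.59 kb, and on chromosome 15 from 76011234 to 76013592, with 2.36 kb. The first of these lay inside the chromosome 1 block shared with WT cells, which held 47 WT peaks. The chromosome 15 peak lay in a cluster that held 4 WT peaks.

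The X chromosome carried about as many H3K9me3 peaks in KO as in WT cells, unlike the autosomes. It held 112 H3K9me3 peaks in WT and 96 in KO, a KO to WT ratio of 0.857, while the autosomes carried 781 and 55158, a ratio of 70.6. The X density in WT was 0.694 peaks per Mb, or 2.14 times that of the autosomes, with a 95% Poisson interval on the X count giving 1.76 to 2.57 times. Much of this WT density came from adjacent windows of 1 Mb. Of the 112 peaks, 34 lay in the window from 121000001 and 33 in that from 120000001. The interval takes no account of such clustering, so the ratio does not describe the X as a whole. In KO the X density was 0.595 per Mb, or 0.0259 times (0.0210 to 0.0316 times). KDM4B was also sparse on the X, at 2.84 peaks per Mb or 0.216 times the autosomal density (0.197 to 0.237 times). WT H3K9me3 peaks were found in the KO list about as often on the X, 48.2% (38.7 to 57.9%), as on the autosomes, 42.4% (38.9 to 45.9%), and these intervals overlap. The Y chromosome had 50 H3K9me3 peaks in WT and 47 in KO.

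**Figure D2:**
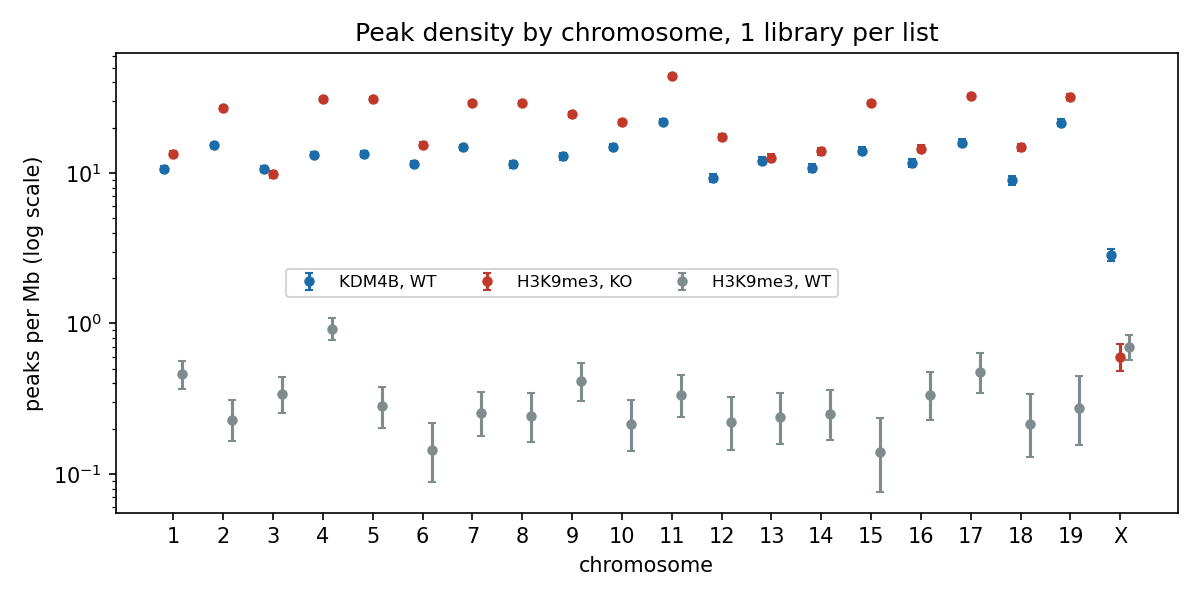
Peaks per Mb (y axis, log scale) on each autosome and the X chromosome (x axis) for KDM4B in WT, H3K9me3 in KO and H3K9me3 in WT, 1 library each, with 95% Poisson intervals. H3K9me3 in KO lies between 9.76 and 44.2 per Mb on the autosomes and at 0.595 per Mb on the X, beside 0.694 per Mb for H3K9me3 in WT.

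The third comparison asked whether H3K9me3 in cells without KDM4B lay where KDM4B had been bound. Of the 32017 KDM4B peaks of WT cells, 7284 overlapped an H3K9me3 peak of KO cells, or 22.8% (95% exact binomial interval 22.3 to 23.2%). Circular shifts of the KDM4B list along each chromosome gave a mean of 729 overlaps, and none of 1000 shifts passed 989, so the observed number was 9.99 times the chance mean. The share was 23.0% (22.6 to 23.5%) on the autosomes and 2.40% (1.205 to 4.26%) on the X chromosome, where 11 of 458 KDM4B peaks overlapped and chance gave a mean of 0.267. In WT cells the same KDM4B peaks overlapped H3K9me3 in 17 cases, or 0.0531% (0.0309 to 0.0850%). Chance placement gave a mean of 13.1 there, and 226 of 1000 shifts reached 17, so this overlap did not stand apart from chance. That share was 0.0250 to 0.131% over the alternative settings. The excess over chance in KO cells was present in each of 4 width classes of KDM4B peaks, from 8.78 times in the narrowest, 237 to 329 bp, to 10.7 times at 510 to 870 bp. Shifts of only 20 to 100 kb, which keep dense regions in place, lowered the ratio to 3.80, and counting peaks within 1 kb of each other as overlapping lowered it to 6.11.

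H3K9me3 peaks of KO cells were concentrated at KDM4B peak centres. In the 250 bp on the lower and on the higher coordinate side of KDM4B midpoints there were 72.8 and 70.8 KO peak midpoints per 1000 KDM4B peaks, against a chance mean of 5.96 and 5.98. Between 4750 and 5000 bp on the higher side there were 18.7, still above the highest of 100 chance placements, 7.90. Seen from the mark, 8706 of the 55306 KO peaks overlapped a KDM4B peak, or 15.7% (15.4 to 16.0%), and 31.5% lay within 5 kb of one, whereas 59.6% lay more than 10 kb from any. The 100 densest windows of the KDM4B list and of the KO H3K9me3 list had 37 windows in common, where 4.51 are expected for independent lists.

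**Figure D3:**
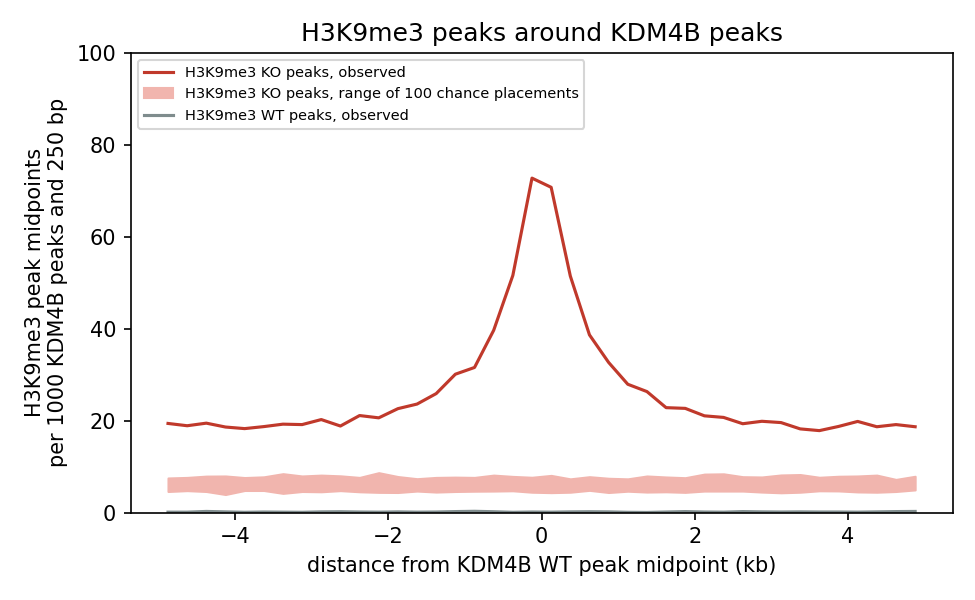
Number of H3K9me3 peak midpoints per 1000 KDM4B WT peaks in bins of 250 bp (y axis) by distance from the KDM4B peak midpoint in kb (x axis), for the KO and WT H3K9me3 lists, with the range of 100 chance placements for KO as a band. The KO line reaches 72.8 next to the midpoint and levels off near 18.7 at the edge, above the band.

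Among regions where both marks met, the widest KO H3K9me3 peak overlapping KDM4B was on the X chromosome from 166426369 to 166429296, with 2.93 kb, and it also overlapped 2 WT H3K9me3 peaks. A cluster on chromosome 15 between 75999977 and 76019912 held 18 KDM4B peaks, 16 KO and 4 WT H3K9me3 peaks. It supplied 5 of the 17 KDM4B peaks that overlapped H3K9me3 in WT cells. The next widest KO peak overlapping KDM4B, on chromosome 1 from 90172316 to 90175080, with 2.77 kb, overlapped no WT H3K9me3 peak but lay inside the shared chromosome 1 block. Other such regions with KO peaks only were on chromosome 14 from 69901866 to 69903633, with 1.77 kb, and on chromosome 6 from 65621207 to 65622933, with 1.73 kb.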

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

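The tests of X copy number, of the X ratio to KDM4B peaks and of more permissive calling were chosen after the result was seen. The KO to WT ratio of H3K9me3 peak numbers was 0.857 on the X chromosome and 70.6 on the autosomes, and this difference was not tested because there is 1 library per genotype. A shortage of the kind of region that KDM4B marks does not account for it alone, since the X had 0.210 KO H3K9me3 peaks per KDM4B peak (0.166 to 0.262) against 0.919 to 2.54 on the autosomes, and removal of X peaks from the KO list is argued against by the 48.2% of WT peaks on the X that were found there. A candidate explanation is that the X is present in 1 copy, as in male cells, so that weak peaks stay under the calling threshold: in the last window of the X, from 166000001, whose end holds the segment shared with the Y, KO peaks absent from WT reached 32.5 per Mb (19.6 to 50.7) against 0.168 per Mb (0.111 to 0.244) on the rest of the X. In that window, chosen after its peaks were seen, WT H3K9me3 peaks already numbered 23.9 per Mb (13.1 to 40.2), against 0.609 per Mb on the rest of the X. Of 2120 autosomal windows of 1 Mb, 11 held at least as many, 14, with up to 47, though the X window spans only 0.585 Mb. KDM4B peaks numbered 13.7 per Mb (5.91 to 27.0) in the X window, against 2.80 on the rest of the X. This lay within the range of 8.94 to 21.9 for whole autosomes, not for single windows. H3 also had 1 peak in the last window of the X in each genotype. Copy number and repeated sequence at the tip therefore cannot be told apart, and a biological difference of the X stays open. The missing gain was not particular to the X: the Y, over a span of 2.56 Mb, had 50 H3K9me3 peaks in WT and 47 in KO. Its KO density of 18.4 per Mb lay within the autosomal range of 9.76 to 44.2, and the Y was not used to weigh copy number.

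The KO H3K9me3 list was 58.6 times as long as the WT list. Whether the KO list is the WT profile called more permissively is not decided. Of the WT peaks, 43.5% (40.3 to 46.7%) were in the KO list, below the bound of 75% that had been set for arguing against it. With 1 library per genotype, however, the share expected between libraries of the same genotype is not known. The peaks used were also changed after the values were seen, from all WT peaks to those of 1 kb or more, and back. Those of 1 kb or more leave it undecided. The share was 16.0% for WT peaks under 300 bp, 60.7% (55.9 to 65.4%) from 300 bp to under 1 kb and 86.7% (78.4 to 92.7%) at 1 kb or more, so it stayed below that bound for all peaks of 300 bp or more, 65.6% (61.3 to 69.7%), but not for the widest alone, and 353 of the 533 WT peaks not found were under 300 bp. Whether the added peaks lie in repeat-like regions cannot be told apart from other causes by the regions that H3 or the KDM4B antibody recovered in KO cells: 0.163% of KO peaks lay within 10 kb of one, but these surroundings span 0.790 Mb and have no room for most of the list. Differences in depth or threshold stay open, and so do the spike-in, the control and the loss of KDM4B itself, which were not tested.

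H3K9me3 peaks were also called on the mitochondrial sequence, which carries no histones: 5 peaks in the KO list covered 10.9 kb, or 66.9% of the 16.3 kb up to the last peak end, and the WT list had 0. The H3 WT list held 2 mitochondrial peaks, and the H3 KO and both KDM4B lists held 0. Signal other than the mark therefore entered the KO H3K9me3 list, and how many of its 55306 peaks, and how much of the ratio of 58.6, come from such signal is not known.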

How the results depend on the processing

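The limit at the median width, the shifts of 20 to 100 kb and the leaving out of regions near H3 or KDM4B KO peaks were chosen after seeing the data. Of 107 alternative values for 27 results, 80 stayed within 1.5 times a count or length or within the counting interval of a share or ratio, and 27 moved further. A change of direction was counted only where the first value's interval excluded 1, and there were 0 of these. That restriction was set after 3 values had crossed 1: the ratio to chance of KDM4B peaks in WT H3K9me3, 1.30 (0.756 to 2.08), went to 0.970 with merging, 0.840 with the width limit and 0.863 with 50% overlap, so its side of 1 is not stable. The cause of the moves below was not tested unless the setting itself shows it. Merging peaks within 1 kb lowered the WT H3K9me3 number to 611; it gave 36.5% and 16.3 times chance for WT peaks in KO, 28.3% and 9.19 times for KDM4B in KO H3K9me3, and 0.245 for the X to autosome density of KDM4B. Autosomes alone gave 22.6 times for WT peaks in KO. Requiring 50% of the shorter peak gave 32.0 times for WT in KO, 19.1% and 11.2 times for KDM4B in KO H3K9me3, and 0.0281% for KDM4B in WT H3K9me3. Counting peaks within 1 kb as shared gave, for the same comparisons, 53.6% and 11.4 times, 34.6% and 6.11 times, and 0.131%, and 1 H3 KO peak near a KDM4B WT peak in place of 0. Peaks at or above the median width gave 61.9% and 44.4 times, 23.3% and 13.5 times, 0.0250%, and an X density ratio of 0.194 for KDM4B. Leaving out regions near H3 or KDM4B KO peaks gave 39.3% of WT peaks in KO, and shifts of 20 to 100 kb gave 7.97 times for WT in KO and 3.80 times for KDM4B in KO H3K9me3. The median score left 20 H3 WT peaks by construction. It was not run on the other 5 lists, which hold no scores, and the alternatives by gene feature and gene list were not run without an annotation of the build. No paired analysis was possible because each group has 1 library. Unknown depth limits every comparison of peak numbers.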

Other observations

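The windows named here and the short shifts were chosen after seeing the data. The densest H3K9me3 window of WT cells was chromosome 1 from 90000001 to 91000000, with 47 WT and 62 KO peaks. Of the 10 densest WT windows, 6 had fewer KO than WT peaks and 4 had more. Those with fewer were chromosome 3 from 25000001 (34 WT and 10 KO), chromosome 4 from 146000001 (34 and 7), the X from 121000001 (34 and 17) and from 120000001 (33 and 18), the Y from 1000001 (24 and 9) and chromosome 4 from 121000001 (21 and 4). Besides chromosome 1, those with more were chromosome 9 from 3000001 (28 WT and 31 KO), chromosome 4 from 152000001 (26 and 56) and the Y from 2000001 (26 and 38).

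Density shared over regions wider than the shifts did not alone account for the meeting of KDM4B peaks with KO H3K9me3 peaks. The observed number was 3.80 times the mean after shifts of 20 to 100 kb. Such shifts cannot address density shared on scales under 20 kb. Loss of the demethylase and recovery of accessible or GC-rich DNA in both libraries stay open, and neither was tested. Of the KO peaks, 59.6% lay more than 10 kb from any KDM4B peak, a share that was not set against chance placement.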
